A study of Homo sapiens with 6 samples.

How the data were processed

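Total RNA was measured in 6 libraries of ARP-1, an established human multiple myeloma cell line at passage 12, per the labels. Cells were treated for 16 h with DMSO, the solvent, or with carfilzomib (Cfz), an irreversible proteasome inhibitor that binds the subunit encoded by PSMB5. The titles put 3 libraries in each group. RNA was isolated with a column kit and made into Illumina libraries, per the labels' protocols, which name neither a poly(A) or ribosomal RNA selection nor a stranded kit. The Cfz dose is not in the labels.

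The deposited tables hold an expected count, an FPKM value and a mean transcript length per Entrez gene, per the file headers. The genome build was hg19, per the submitters' processing notes. The aligner, the counting tool and the annotation release are not given in the sources used here. Expected counts are estimates in which reads shared between transcripts are divided, so between 79.0% and 80.0% of the deposited values of a library were whole numbers exactly as written, with no tolerance. FPKM in the deposited tables is a count scaled to transcript length and library total, per the file headers' names. Each library's table lists only genes with a count above 0, and a gene missing from a table was taken as 0. Of 15911 genes listed in at least 1 library, 12787 were listed in all. All 15911 carried a RefSeq mRNA accession, so non-coding genes were not measured here, and 0 genes of the mitochondrial genome were listed. A table of the whole series with 6 value columns was not used. The reference genome given for this work is a later build than hg19, so no coordinates are printed. Its transcripts (GENCODE 29) were used for GC content, matched by accession for 15628 genes and by symbol for 142, with 141 unmatched.

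Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, a quasi-likelihood fit and its F test of Cfz against DMSO, two-sided. Genes with a mean of at least 1 CPM (counts scaled to the library total) over the 6 libraries were tested, 11025 in all. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of F. The comparison, the filter, the gene lists and the rule for naming genes were fixed before the data were examined. The rule named PSMB5. It also named the 5 largest rises and the 5 largest falls among changed genes whose groups did not overlap and whose mean FPKM was at least 5 in the higher group. For 11 lists it named the 2 members with the largest change in the direction that most changed members took, and for each other list past the list test 1 member. This gave 31 genes, of which 30 are reported and 1 is not reported here, and a gene could be named by more than 1 part. Further list members are named in the text as examples, and these were chosen after their values were seen.

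The 26 response lists covered the proteasome, the immunoproteasome and antigen processing, the ubiquitin pathway, heat shock, endoplasmic reticulum (ER) chaperones, the ATF4 and CHOP response, tRNA synthetases, the NRF2 response, metallothioneins, autophagy and apoptosis. They further covered p53 targets, immediate early genes, DNA replication, G2/M, homologous recombination, ribosome biogenesis, ribosomal proteins, the respiratory chain, cholesterol synthesis and glycolysis. The last were NF-kB targets, interferon-stimulated genes, plasma cell identity, histones and chromatin enzymes. A further 8 check lists held common reference genes, mitochondrially encoded transcripts and markers of T and NK cells, myeloid cells, earlier B cells, erythroid cells and platelets, fibroblasts and epithelium. Lists with at least 5 tested members, 25 in all, were compared with the other genes by camera (limma 3.58.1). It ran on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with p adjusted over the 25 lists. Camera with an estimated correlation was run beside it, as was fry, which tests whether a list's genes move, on balance, 1 way, without comparing them with other genes. Symbols and older symbols were matched through name tables.

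The pipeline was tested on simulated data made from the means and library sizes of the 6 libraries over the 11025 genes. Of 50 genes changed at each size, it recovered 32% at 1.5-fold, 84% at 2-fold, 100% at 4-fold and 100% at 8-fold, with 9 false calls among 167. Of 100 lists of unchanged genes, 0 were called by camera. Genes were simulated independently of each other, with few changed, equal numbers raised and lowered, and no GC trend. False calls with correlated genes, with many genes changed mostly 1 way or with a GC trend were therefore not tested. Library totals lay between 25268871 and 26867194 expected counts. A count of 3, the upper limit that a count of 0 allows, corresponded to 0.112 to 0.119 CPM. Such floors cover counting error only. The chi-square per degree of freedom was at least 1.72 for every pair of replicates, so no pair agreed within sampling noise and each library was counted separately. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

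The alternatives left out each library in turn, added the replicate number as a block, removed or raised the filter on low counts (to a mean of 5 CPM) and used a threshold of 0.01. Others used DESeq2 1.42.0, limma on log2(FPKM + 1), DESeq2's size factors in edgeR, the library size alone, or a scaling to the reference genes. After the data were seen, a correction of every library for GC content (loess, span 0.3), the same correction of DMSO 2 alone, and limma voom with sample quality weights were added. Mean transcript lengths were tested with limma on log2 length for 5348 genes with a mean of at least 10 CPM. These were listed in every library, and genes with the same length in all 6 libraries were left out. Gene Ontology terms deposited with the genes were tested with a one-sided Fisher's exact test among 8784 tested genes with a term, over 1374 terms of 10 to 300 genes. Figures were drawn with matplotlib 3.10.9.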

Results

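The transcriptome of ARP-1 myeloma cells was profiled after 16 h with DMSO (n = 3 libraries) or with the proteasome inhibitor Cfz (n = 3 libraries), to describe how these cells respond to Cfz. Total expected counts were 25827589, 26867194 and 25844625 in DMSO 1 to 3 and 25268871, 26196076 and 25524503 in Cfz 1 to 3. Between 14030 and 14275 genes were listed per library. The 10 most abundant genes held 5.03% ± 0.367 of the counts in DMSO and 7.27% ± 0.035 in Cfz (SD, n = 3 each), and GAPDH was the most abundant gene in every Cfz library, at 1.28% to 1.33%.

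The first principal component of the tested genes held 84.1% of the variance and separated the groups. The second held 12.6% and set library DMSO 2 (32.8) apart from DMSO 1 (−19.8) and DMSO 3 (−20.7). Across genes, which are not independent replicates, the deviation of DMSO 2 from the other DMSO libraries followed transcript GC content, with a Spearman correlation of 0.86. Its median deviation was −1.0 (log2) in the 10% of genes lowest in GC and 0.28 in the 10% highest.

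**Figure D1:**
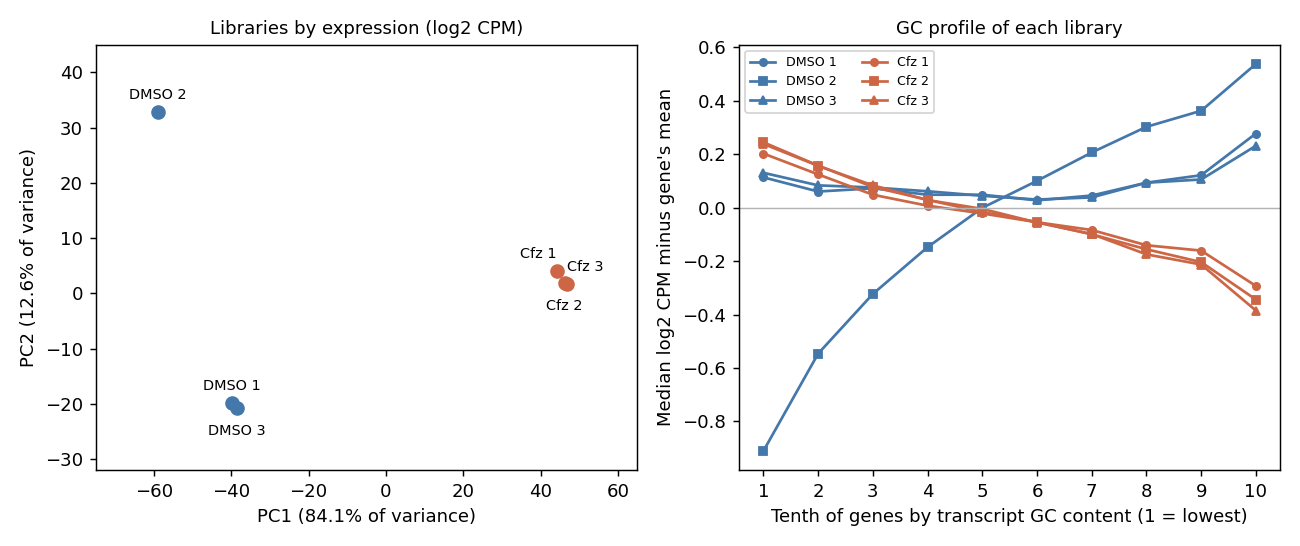
Left, each library on the first and second principal components of log2 CPM (84.1% and 12.6% of variance). Right, median log2 CPM minus the gene's mean over libraries (y) for 10 bins of genes by transcript GC content (x), with 1 line per library, where DMSO 2 rises most steeply with GC and the Cfz libraries fall.

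Cfz changed the expression of 6747 of 11025 tested genes (61.2%), with 2695 higher and 4052 lower. Most tested genes of the proteasome (32 of 41), the cytosolic heat shock response (23 of 29) and autophagy (24 of 34) rose, and most of ribosome biogenesis (34 of 43) fell. These 4 lists stood apart from other genes in camera, also with an estimated correlation (adjusted p = 0.0218 each). Camera called 6 further lists, and these calls were lost with an estimated correlation. They were the ubiquitin pathway, ATF4 and CHOP targets, the NRF2 response and interferon-stimulated genes (higher) and plasma cell identity (lower), each with an adjusted p = 0.0716, and DNA replication (lower), with an adjusted p = 0.111. The estimate lay below the preset 0.01 for plasma cell identity (−0.023), interferon (−0.019), replication (−0.015) and ubiquitin (0.0067). Correlation between genes thus cannot account for the loss of those calls. For ATF4 and CHOP (0.024) and NRF2 (0.070) the estimate lay above it. In the proteasome list the estimate (−0.011) lay below it, yet camera's adjusted p went from 8.37e-11 to 0.0218. The version with an estimate was thus far less sensitive whatever the estimate. How far correlation accounts for the loss of the ATF4 and CHOP and NRF2 calls was not tested. At least 2-fold changes were found for 2118 genes, 759 higher and 1359 lower, and 4278 genes did not pass the test. Calls were made with edgeR's quasi-likelihood test. The 3 libraries of each group did not overlap for 7989 tested genes (72.5%, against 10% by chance), among them 6668 of the changed genes.

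The balance of directions depended on library DMSO 2 and on the scaling. Without DMSO 2, 4564 genes were higher and 4607 lower, and 6573 genes were called in both fits, all in the same direction. The share of changed genes that were higher was 39.9%, against 48.2% with DESeq2's size factors, 36.0% with library size only and 22.5% when libraries were scaled to common reference genes, which moved the median of all genes by −0.27 (log2). With that scaling the medians of the ubiquitin (0.12), ATF4 and CHOP (0.37), autophagy (0.37) and interferon (0.24) lists were lower, and those of plasma cell identity (−0.67) and replication (−0.64) farther below 0. Among those 23 reference genes 11 rose and 6 fell (11 and 7 adjusted over the list alone), and GAPDH went from 6086 ± 601 to 13059 ± 241 CPM (SD, n = 3 each).

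Among changed genes with a mean of at least 5 FPKM in the higher group, the 5 largest rises included an inflammasome sensor and an antiviral gene. AIM2 (Entrez gene 9447), a sensor of cytosolic DNA, rose 46.9-fold, by 5.55 ± 0.24 on the log2 scale (SE), from 0.197 ± 0.119 to 8.59 ± 0.474 FPKM (SD, n = 3 each). The interferon-stimulated OASL (8638) rose by 5.03 ± 0.21, and the cystine transporter gene SLC7A11 (23657) by 4.72 ± 0.36, from 0.943 ± 0.405 to 23.9 ± 0.464 FPKM. MLLT11 (10962) rose by 4.69 ± 0.15 and ATF3 (467), a stress-induced transcription factor, by 4.66 ± 0.16. With the same minimum, the largest falls were those of FJX1 (24147), at −4.44 ± 0.16, and of EGR1 (1958), an immediate early transcription factor, which went from 58.1 ± 5.75 to 3.28 FPKM (−4.09 ± 0.09). RASGRP2 (10235, a Rap activator, −3.96 ± 0.16), PTPRCAP (5790, a CD45-associated protein, −3.83 ± 0.15) and JAKMIP1 (152789, −3.80 ± 0.15) followed. For all 31 genes named by the fixed rule, the highest adjusted p of edgeR's quasi-likelihood test was 0.00123, and all 3 libraries of the higher group lay above all 3 of the other. The rule itself took all of them but PSMB5 from called genes. It also required groups that did not overlap for the 5 largest rises and 5 largest falls.

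**Figure D2:**
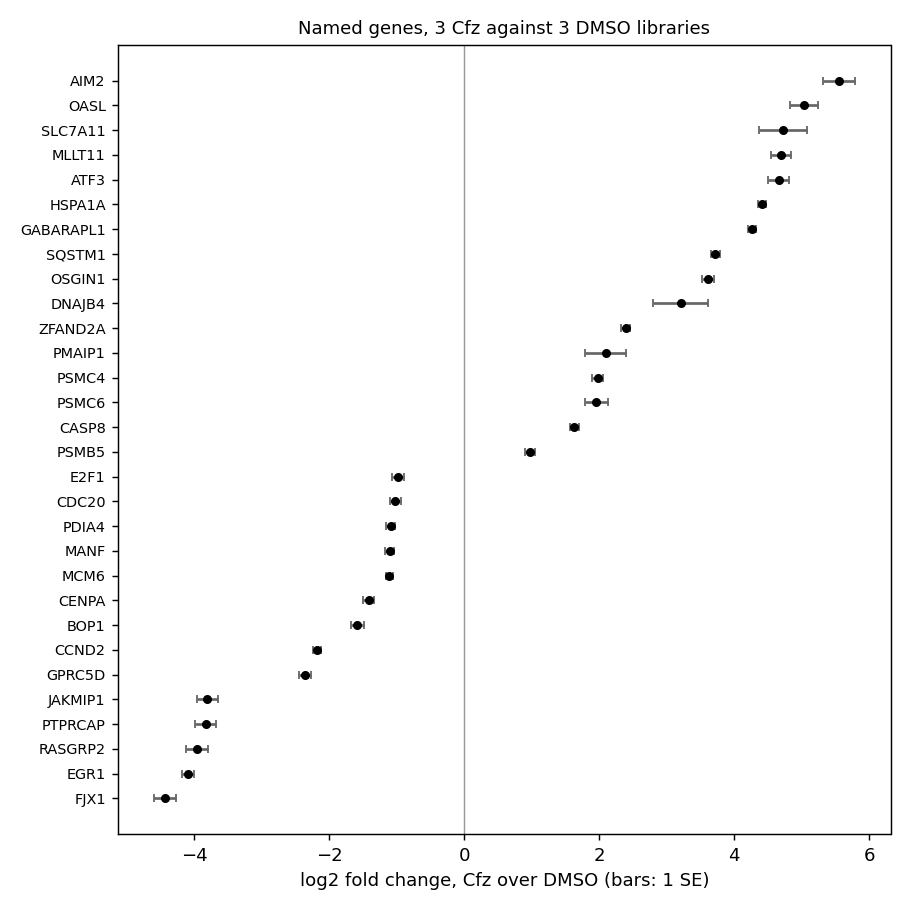
Log2 fold change of Cfz over DMSO (x) with 1 standard error (bars) for 30 of the genes named by the fixed rule (y), from 3 libraries per group. Values run from −4.44 for FJX1 to 5.55 for AIM2, and every bar lies clear of 0. All but PSMB5 were named from genes already called changed.

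Most genes of the drug's target complex rose. PSMB5 (5693), whose product Cfz binds, rose 1.97-fold, from 70.5 ± 5.91 to 136.3 ± 5.84 FPKM (log2 0.98 ± 0.07 SE, adjusted p = 7.15e-05 by edgeR's quasi-likelihood test). Of 41 proteasome genes, 32 rose, 3 fell and 6 did not pass, and the counts were the same adjusted over the list alone. The median log2 change was 1.21. The ATPase subunit genes PSMC4 (5704) and PSMC6 (5706) rose by 1.98 ± 0.08 and 1.96 ± 0.17. With GC correction of every library they rose by 2.25 and 1.525. The 3 members that fell were PSMG1, PSMG3 and PSMG4, which encode assembly chaperones of the core particle. The list stood apart from other genes (camera, adjusted p = 8.37e-11) and did so as well with an estimated correlation (adjusted p = 0.0218).

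Of 17 genes of the immunoproteasome and antigen processing, 12 fell and 3 rose, the same counts adjusted over the list alone, with a median of −0.38. PSMB9, an inducible catalytic subunit, changed by −1.56 and NLRC5, an activator of MHC class I genes, by −1.45, whereas ERAP2 rose by 1.30. With GC correction 4 rose and 7 fell, with a median of −0.069, and without DMSO 2 the median was −0.24. The list did not stand apart from other genes (camera, adjusted p = 0.124, and 0.71 with an estimated correlation).

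**Figure D3:**
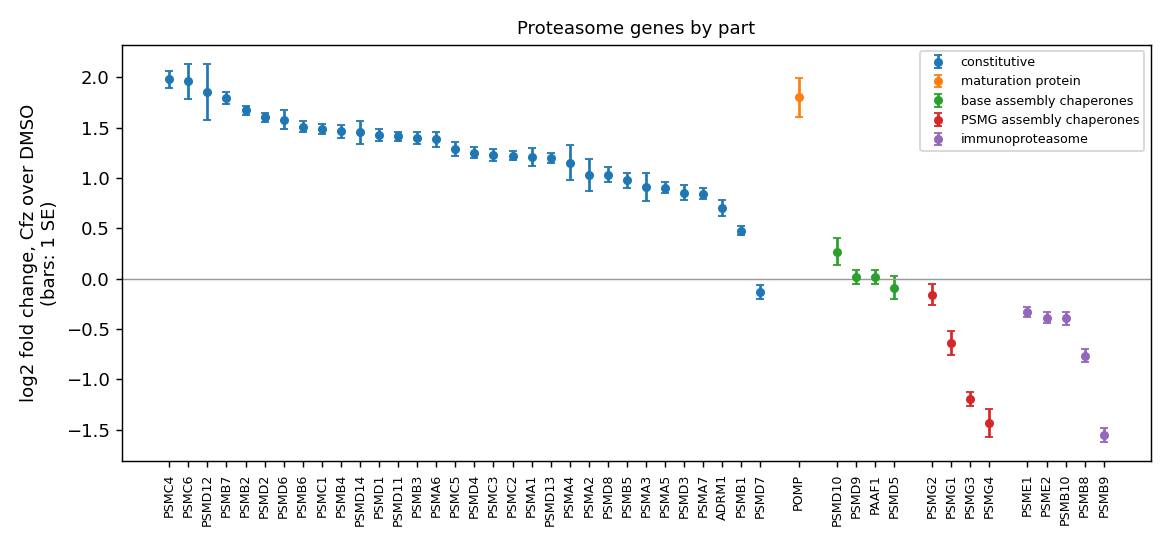
Log2 fold change of Cfz over DMSO (y) with 1 standard error (bars) for each proteasome gene (x), coloured by part of the complex, from 3 libraries per group. Of 32 constitutive subunit genes 31 were called higher, 3 of 4 PSMG chaperone genes lower and 5 of 5 immunoproteasome genes lower.

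Among 26 genes of the ubiquitin pathway, 13 rose and 6 fell (14 and 6 adjusted over the list alone), with a median of 0.37. ZFAND2A (90637), a stress-induced proteasome-associated protein gene, rose 5.25-fold (2.39 ± 0.07). UFD1, a cofactor of the segregase VCP, rose by 1.87. The list passed camera (adjusted p = 0.00293), though not with an estimated correlation (adjusted p = 0.0716).

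Of 29 cytosolic heat shock genes, 23 rose and 2 fell, also adjusted over the list alone, with a median of 0.91. The inducible HSP70 gene HSPA1A (3303) rose 21.3-fold (4.41 ± 0.06) to 553.5 FPKM. HSPA1B, nearly identical in sequence, rose by 3.19, and how reads were divided between both is uncertain. The co-chaperone gene DNAJB4 (11080) rose by 3.21 ± 0.41 and BAG3 by 2.56. With GC correction of every library DNAJB4 rose less, by 2.66, and HSPA1A more, by 4.82. Camera called the list higher (adjusted p = 9.65e-08, and 0.0218 with an estimated correlation).

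The ER chaperone genes went both ways. Of 31 tested, 9 rose and 13 fell, also adjusted over the list alone, with a median of 0.0030 (camera, adjusted p = 0.967). The secreted stress factor MANF (7873) fell by 1.10 ± 0.07 on the log2 scale and the disulfide isomerase gene PDIA4 (9601) by 1.09 ± 0.07, from 237.1 to 107.2 FPKM. HSPA5, the main ER chaperone gene, changed by −0.20, and ERN1, the gene of the sensor IRE1, by 1.13. Without DMSO 2, 17 rose and 13 fell, with a median of 0.11, and the median was −0.26 when scaled to the reference genes.

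Of 32 targets of ATF4 and CHOP, 22 rose and 5 fell (22 and 6 adjusted over the list alone), with a median of 0.64. Besides ATF3 and SLC7A11, the glutathione-degrading CHAC1 rose by 3.04 and DDIT3, which encodes CHOP, by 1.17. The list was called higher by camera (adjusted p = 2.79e-05), though not with an estimated correlation (adjusted p = 0.0716). Of 20 cytosolic tRNA synthetase genes, 5 rose and 9 fell, also adjusted over the list alone (camera, adjusted p = 0.973). Their median was −0.11 (−0.051 without DMSO 3), whereas camera's direction was up, and both were near 0.

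Of 23 genes of the NRF2 antioxidant response, 19 rose and 2 fell (19 and 3 adjusted over the list alone), with a median of 1.18. OSGIN1 (29948), an oxidative stress-induced growth inhibitor, rose 12.2-fold (3.61 ± 0.09) and HMOX1, heme oxygenase, by 3.26. Camera called these genes higher (adjusted p = 9.65e-08), though not with an estimated correlation (adjusted p = 0.0716). Both tested metallothionein genes fell, MT2A by 1.23 and MT1X by 1.26 on the log2 scale, and reads can be shared within that family.

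Of 34 genes of autophagy and the lysosome, 24 rose and 3 fell (26 and 3 adjusted over the list alone), with a median of 0.63. GABARAPL1 (23710), an ATG8 family member, rose 19.1-fold (4.26 ± 0.06) from 7.15 to 131.7 FPKM. The receptor gene SQSTM1 (8878), which encodes p62, rose 13.2-fold (3.72 ± 0.07) from 39.3 to 498.2 FPKM. The list passed camera (adjusted p = 5.38e-07, and 0.0218 with an estimated correlation).

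Of 27 apoptosis regulators, 12 rose and 6 fell, also adjusted over the list alone, with a median of 0.23, and the list did not pass camera (adjusted p = 0.0685), though it did with GC correction of every library (adjusted p = 0.0439, from 0.0414 to 0.163 over its camera alternatives). PMAIP1 (5366), which encodes the BH3-only protein NOXA, rose 4.27-fold (2.09 ± 0.31) and CASP8 (841) 3.09-fold (1.63 ± 0.07). With GC correction of every library PMAIP1 rose by 1.68 and CASP8 by 1.57. MCL1, the anti-apoptotic partner of NOXA, changed by 0.81 and BCL2 by −1.28, both past the threshold. Of 23 p53 targets, 8 rose and 7 fell, also adjusted over the list alone (median 0.24, camera, adjusted p = 0.188). Without DMSO 2, 14 p53 targets rose and 8 fell, with a median of 0.17. CDKN1A, the p21 cell cycle inhibitor gene, rose by 3.58. Scaled to the reference genes, the medians of both lists were −0.026 and −0.014.

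Most genes that mark plasma cells and myeloma fell. Of 34, 20 fell and 4 rose, also adjusted over the list alone, with a median of −0.41. GPRC5D (55507), a surface receptor of plasma cells, went from 166.1 to 31.2 FPKM (−2.36 ± 0.09), and the cyclin gene CCND2 (894) from 85.2 to 18.1 FPKM (−2.18 ± 0.06). IRF4, a plasma cell transcription factor, changed by −0.89 and SDC1, which encodes CD138, by −2.12. The list was called lower by camera (adjusted p = 0.0037), though not with an estimated correlation (adjusted p = 0.0716).

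Ribosome biogenesis genes fell as well, 34 of 43, while 2 rose, also adjusted over the list alone, with a median of −0.65. BOP1 (23246), a pre-rRNA processing factor, changed by −1.58 ± 0.10, and by −0.84 after correction of every library for GC content. MYC changed by −1.19. Camera called the list lower (adjusted p = 7.34e-07, and 0.0218 with an estimated correlation). Of 71 cytosolic ribosomal protein genes, 4 rose and 19 fell (2 and 17 adjusted over the list alone), with a median of −0.051 (camera, adjusted p = 0.445). Without DMSO 2, 41 rose and 14 fell, with a median of 0.086, and the median was 0.032 with DESeq2's size factors. Scaled to the reference genes the list passed, with a median of −0.32 (camera, adjusted p = 0.00683, from 0.00683 to 0.986 over its camera alternatives).

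Of 45 genes of DNA replication and S phase, 27 fell and 7 rose (27 and 8 adjusted over the list alone), with a median of −0.37. The helicase gene MCM6 (4175) changed by −1.11 ± 0.05, and the transcription factor gene E2F1 (1869) by −0.98 ± 0.09, or −0.42 after correction for GC content. RRM2, a ribonucleotide reductase subunit gene, rose by 1.37. Camera gave an adjusted p of 0.0393. The list did not pass with an estimated correlation (adjusted p = 0.111) or without Cfz 1 (adjusted p = 0.0543), over camera alternatives that ranged from 0.0120 to 0.111. Without DMSO 2 the median was −0.23, and with GC correction −0.22.

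Of 49 genes of G2/M and mitosis, 6 rose, 14 fell and 29 did not pass (5 and 12 adjusted over the list alone), with a median of −0.025 (camera, adjusted p = 0.967). The centromere histone gene CENPA (1058) changed by −1.41 ± 0.08 and CDC20 (991), an activator of the anaphase-promoting complex, by −1.02 ± 0.09. Without DMSO 2, 21 rose and 17 fell, with a median of 0.027, and the median was 0.064 with DESeq2's size factors. In the other direction, 12 rose and 22 fell with GC correction of every library (median −0.117). Scaled to the reference genes, 2 rose and 27 fell (median −0.285). Of 31 genes of homologous recombination and the Fanconi pathway, 2 rose and 12 fell, also adjusted over the list alone (median −0.13, camera, adjusted p = 0.338). In DMSO 2 the median deviation of that list was −0.39, and without this library 6 rose and 15 fell. The median was −0.027 without DMSO 1 and −0.080 without DMSO 3. With GC correction of every library 4 rose and 20 fell, and the list passed, with a median of −0.28 (camera, adjusted p = 0.00624, from 0.00624 to 0.839 over its camera alternatives).

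Of 23 interferon-stimulated genes, 13 rose and 3 fell, also adjusted over the list alone, with a median of 0.51. Besides OASL, IFIT3 went from 24 to 902 counts and IFI44 from 7 to 515 counts, each summed over 3 libraries. IFIT2 had 0 counts in DMSO and 324 in Cfz, at least 114-fold higher against a floor of 3 counts over the group, and the list's median was 0.51 with that bound in place. OAS2 changed by −1.52, and ISG15 by −0.18 without passing. With GC correction of every library 15 rose and 1 fell. These genes passed camera (adjusted p = 0.0039), though not with an estimated correlation (adjusted p = 0.0716). Summed over T and NK cell and myeloid markers, 20.7 ± 0.98 CPM were found in DMSO and 21.7 ± 1.09 in Cfz (SD, n = 3 each). That sum held opposite moves. Mean CPM went from 9.22 to 8.01 for GNLY and from 1.96 to 0.65 for ZAP70. It went from 1.99 to 3.10 for KLRD1 and from 4.23 to 6.18 for CD68.

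Other lists held members that moved strongly in both directions. Of 26 immediate early genes, 11 rose and 10 fell, also adjusted over the list alone (median 0.12, camera, adjusted p = 0.338), with JUN at 3.69 and ATF3 at 4.66 against EGR1 at −4.09. Of 17 NF-kB targets, 7 rose and 3 fell, also adjusted over the list alone (median 0.12, camera, adjusted p = 0.106), and the chemokine gene CCL3 rose by 3.41. Of 24 cholesterol synthesis genes, 10 rose and 7 fell (11 and 7 adjusted over the list alone; median 0.24, camera, adjusted p = 0.188), with HMGCS1 at 1.52 and TM7SF2 at −1.75. Of 23 genes of glycolysis and hypoxia, 12 rose and 7 fell, also adjusted over the list alone (median 0.28, camera, adjusted p = 0.106), with GAPDH at 1.16 and PFKL at −1.60. Scaled to the reference genes, the medians of the immediate early (−0.15), NF-kB (−0.14) and cholesterol (−0.026) lists were below 0. With that scaling 8 glycolysis and hypoxia genes rose and 10 fell, with a median of 0.01. The NF-kB list passed camera without DMSO 2 (median 0.24, adjusted p = 0.0363), with no filter on low counts (median 0.91, adjusted p = 0.00706) and with GC correction of every library (median 0.50, adjusted p = 0.0182), from 0.00706 to 0.356 over its camera alternatives. The glycolysis list passed with GC correction (median 0.38, adjusted p = 0.0361, from 0.0361 to 0.617 over its camera alternatives). Without DMSO 2 the medians of the immediate early, cholesterol and glycolysis lists were 0.30, 0.37 and 0.48. The immediate early median was 0.062 without DMSO 3.

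Of 56 nuclear genes of the respiratory chain, 11 rose and 20 fell, also adjusted over the list alone, and the median of −0.037 and camera's direction, up, differed in sign (adjusted p = 0.967). Of 46 chromatin enzymes, 15 rose and 14 fell, also adjusted over the list alone (median 0.020, camera, adjusted p = 0.338), with KDM3A, a demethylase, at 1.47 and the deacetylase HDAC4 at −1.75. Of 45 listed replication-dependent histone genes, only 8 passed the filter on low counts, so the list says little of these genes as a whole. Of the 8, 1 rose and 1 fell, or 1 and 0 adjusted over the list alone (median 0.059, camera, adjusted p = 0.67). The chromatin and histone medians were −0.25 and −0.20 when scaled to the reference genes. With 1 library left out, the histone median ran from −0.043 (without Cfz 2) to 0.11 (without DMSO 2), the chromatin median from 0.0080 (without Cfz 1) to 0.14 (without DMSO 2) and the respiratory chain median from −0.049 (without Cfz 3) to 0.065 (without DMSO 2). Without DMSO 2, 27 respiratory chain genes rose and 17 fell, and 25 chromatin enzymes rose and 17 fell.

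**Figure D4:**
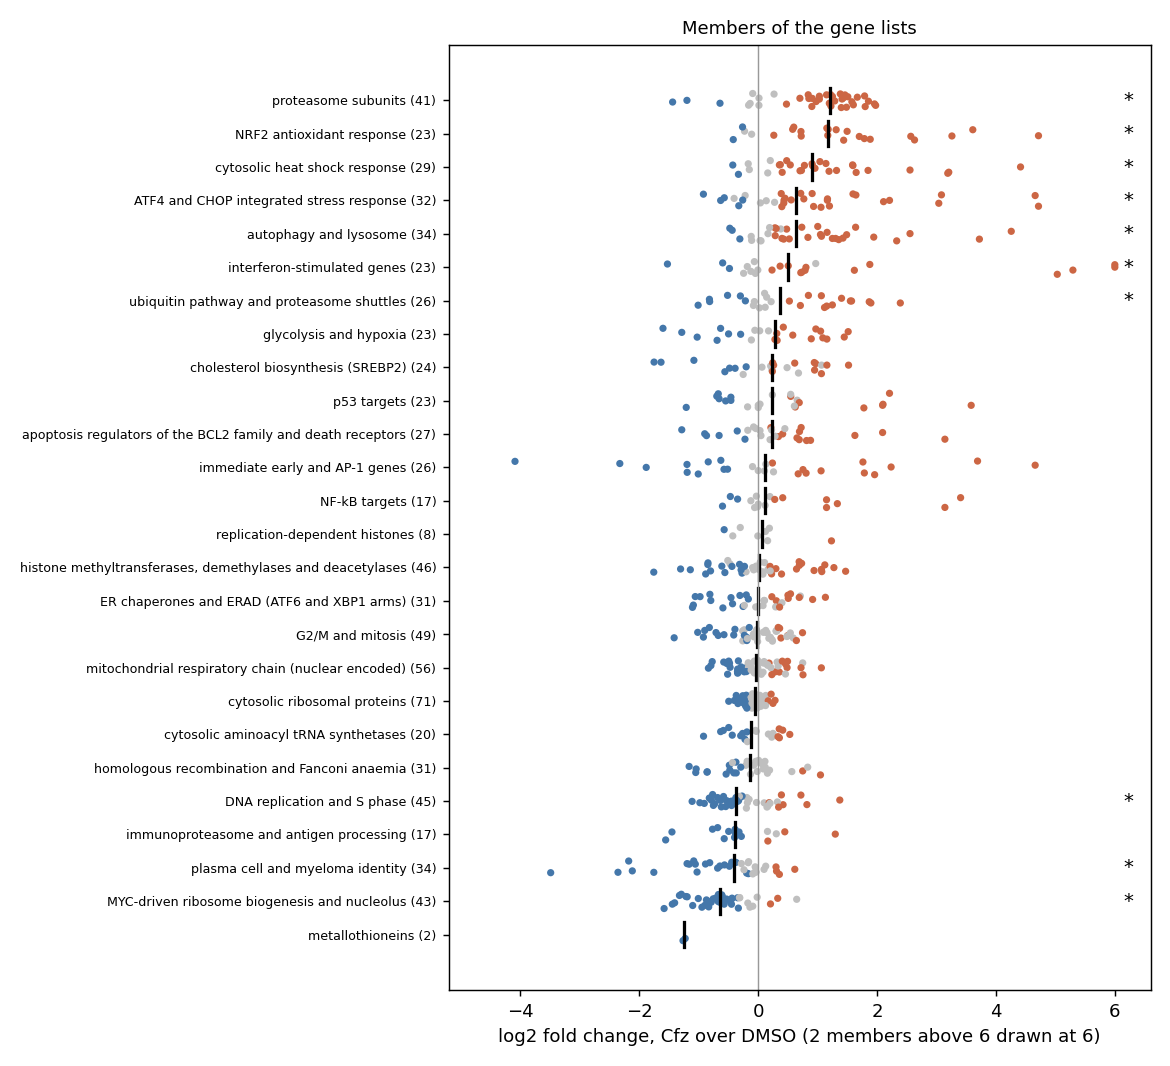
Log2 fold change of Cfz over DMSO (x) of every tested member of the response lists (y, number tested in brackets), orange for called higher, blue for called lower and grey for not past the threshold, with black bars for medians and * for lists past camera. Medians run from 1.21 for the proteasome list to −1.25 for the 2 metallothionein genes, and 2 members above 6 are drawn at 6.

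Few markers of other cell types reached 1 CPM. Of 15 listed T and NK cell markers 3 did, the highest being GNLY at 9.22 ± 0.37 in DMSO and 8.01 ± 0.67 in Cfz (SD, n = 3 each). Of 8 myeloid markers 2 did, with CD68 at 4.23 ± 0.52 and 6.18 ± 0.21. Of 17 markers of earlier B cells 5 did, with BACH2 at 25.4 ± 1.24 and 22.8 ± 1.56. Of 4 erythroid and platelet markers 0 did, the highest being KLF1 at 0.51 and 0.18. Of 9 fibroblast markers 3 did, with VIM at 3349 ± 136 and 2866 ± 17.9, and of 11 epithelial markers 4 did, with KRT18 at 4.40 ± 0.67 and 8.22 ± 0.06.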

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

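The test of transcript lengths was chosen only after the tables had been read. The tables also give a mean transcript length per gene, which depends on the mix of transcripts to which the counts were assigned and entered no comparison of expression. This length differed between Cfz and DMSO for 234 of 5348 genes whose length varied between libraries (limma on log2 length, Benjamini-Hochberg adjusted). Of the 234, 128 were longer and 106 shorter in Cfz, and 1037 of the 5348 had an unadjusted p under 0.05. Most differences were small. Only AGAP1 among the 234 differed by at least 0.5 on the log2 scale (−0.58 ± 0.09 SE), and it did not pass without DMSO 2 (adjusted p = 0.0798). Among other genes chosen after their values were seen, DEF8 went from 1618 ± 22 to 1179 ± 30 bases (SD, n = 3 each) and DENND1A, a regulator of endocytosis, from 4399 ± 48 to 3235 ± 88 bases. HSPA14, an HSP70 family gene, went from 2390 ± 40 to 2799 ± 6 bases.

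Without DMSO 2, 147 genes passed, of which 98 were among the 234, all 98 in the same direction. In simulated lengths for the same 5348 genes, 192 of 200 genes shifted by 0.5 were recovered, with 12 false calls. Only 1 of the 234 called genes differed by that much, so recovery of smaller differences was not tested. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 234 genes. The others gave 0 at most, and 10 splits are too few for a share under 0.05. Every other split mixed Cfz and DMSO libraries in both groups, so a length shift with Cfz widened the spread there. Their 0 calls are thus no measure of chance. The lengths are estimates from short reads, so whether transcripts themselves were exchanged was not tested.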

How the results depend on the processing

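The GC corrections and the voom weights were chosen only after the results were seen; the other alternatives were planned. The 31 named genes kept their direction and their side of the threshold in all 527 alternatives run for them, and their highest adjusted p was 0.0065. All of them but PSMB5 were picked by their changes in the main fit of the same libraries. Their stability therefore says little of the other changed genes. The number of changed genes ranged from 5185 (threshold of 0.01) to 9171 (without DMSO 2). Leaving out 1 library at a time gave 2108 to 4564 genes higher in Cfz, with 4564 without DMSO 2 alone above 2530. Scaling to the reference genes gave 1600 higher and 5505 lower, and GC correction of every library 4127 higher and 4192 lower; of 6028 genes called with and without that correction, 5835 had the same direction. The cause was not tested. Limma on log2(FPKM + 1) gave 1400 genes changed at least 2-fold, on a scale that shrinks low genes. Camera with an estimated correlation passed 4 lists and fry, which makes no comparison with other genes, 20.

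Of the 10 lists past camera, 4 passed under every alternative (proteasome, heat shock, autophagy, ribosome biogenesis). The medians of all 10 kept their sign in every alternative. Of the other 6, 5 were lost with an estimated correlation alone (adjusted p = 0.0716, the highest over their alternatives). Replication was also lost with DESeq2's size factors (adjusted p = 0.0608, from 0.0120 to 0.111 over its camera alternatives). Lists gained a call in 13 planned (10 of them in fry) and 7 added comparisons, among them NF-kB targets without DMSO 2 and ribosomal proteins with reference genes. Fry called immunoproteasome, ER chaperone, tRNA synthetase, G2/M and homologous recombination genes lower. It called apoptosis, p53, immediate early, NF-kB and glycolysis genes higher (fry, adjusted p of 0.0159 at most). For 5 lists that did not pass camera, the direction of the list test, which can differ from that of the median, turned under the settings below. Each setting is given with the list's median log2 change, and the cause was not tested. Cytosolic tRNA synthetases gave −0.119 to −0.051 with 1 library left out (turned without DMSO 2, −0.054), −0.10 with the replicate block, −0.15 in limma, −0.17 with library size only, −0.37 with reference genes, −0.07 and −0.17 with the GC corrections and −0.11 in fry. The respiratory chain gave −0.049 to 0.065 with 1 library left out (turned without DMSO 3, −0.02), −0.091 in limma, −0.092 with library size only, −0.30 with reference genes and −0.037 in fry. ER chaperones gave −0.26 with reference genes, 0.062 with GC correction and 0.003 in fry. Ribosomal proteins gave −0.074 to 0.086 with 1 library left out (turned without DMSO 2, 0.086), 0.008 with no filter, 0.032 with DESeq2's size factors and 0.066 with GC correction. G2/M gave −0.043 to 0.027 with 1 library left out (turned without DMSO 3, 0) and 0.064 with DESeq2's size factors.

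With the replicate number as a block, 6125 genes changed, 2445 of them higher. Deviations of same-numbered libraries correlated across genes at −0.17, −0.065 and 0.154, and not every library correlated best with its own number. Of the 10 splits of the libraries, 1, the real one, gave as many genes changed (6747), higher (2695), lower (4052) or changed at least 2-fold (2118). The others gave 0 at most. Every other split mixed Cfz and DMSO libraries in both groups, so the Cfz effect widened the spread within groups. Their 0 calls are thus no measure of chance. For lists, 4 splits gave 10 or more, with 14 at most, all besides the real one with DMSO 2 among the Cfz libraries. The 6 other splits gave 6 to 9 lists, with 0 genes changed in edgeR. Every split besides the real one divided the Cfz libraries unevenly, so part of the Cfz effect remained in it. These list calls are thus no measure of chance, and how far that remainder accounts for them was not tested. With 10 splits no share can be under 0.05. The 5 alternatives meant for FPKM without counts were not run.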

Other observations

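The Gene Ontology test and all tests of explanations below were chosen only after the results were seen, except those of GC content and transcript length in DMSO 2. Among genes at least 2-fold lower in Cfz, 2 Gene Ontology terms were enriched (one-sided Fisher's exact test, adjusted over 1374 terms). G-protein coupled receptor signaling had 24 of 78 tested members lower against 9.3 expected (adjusted p = 0.00518, 0.0114 without DMSO 2 and 0.00311 with GC correction). They included the phosphatase gene PTPN6 (−2.75 ± 0.08 SE, log2), the exchange factor gene VAV1 (−2.17 ± 0.09), the sphingosine-1-phosphate receptor gene S1PR4 (−2.07 ± 0.11) and the chemokine receptor gene CXCR3 (−1.77 ± 0.17), chosen after their values were seen. Canonical Wnt signaling had 17 of 40 lower (adjusted p = 0.00153, 0.0359 without DMSO 2), among them CCND1 (−3.49 ± 0.12), the co-receptor gene LRP5 (−2.93 ± 0.11) and SDC1 (−2.12 ± 0.09), but not with GC correction (adjusted p = 0.145).

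Among genes at least 2-fold higher, 40 terms were enriched, and 6 of them were also enriched without the genes of the proteasome list. The 6 included the response to unfolded protein (11 of 28, adjusted p = 0.00119 without proteasome genes), protein refolding (6 of 10, 0.0103) and autophagy (17 of 95, 0.0471). Terms such as NIK/NF-kappaB signaling (26 of 48) rested on proteasome genes, and without them its adjusted p was 0.152. CCL4, a chemokine gene below the filter, had 0 counts in DMSO and 23 in Cfz.

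Library DMSO 2 stood apart from DMSO 1 and DMSO 3. Its deviation correlated with transcript GC content at 0.86 across genes, GC content accounted for 69.2% of its variance, and DMSO 1 minus DMSO 3 correlated at 0.179. After GC content was accounted for, the correlation with transcript length was −0.01, which argues against a length bias. Its lowest correlation with another DMSO library was 0.054 above its highest with a Cfz library, and the Cfz libraries correlated with each other at 0.998, which argues against a label exchanged with one of them. The deviation ran against the Cfz effect (−0.147), which argues against RNA of treated cells as its main source, but at 0.051 with GC content taken out of both (0.010 and 0.030 where they shared no library), so a share of such RNA stays open. A difference in how that library was made or amplified may underlie the GC trend, no biological explanation was tested, and whether the Cfz effect's own correlation with GC content (−0.267 without DMSO 2) is technical stays open.

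Interferon-stimulated genes rose in part. Cells of the 6 types with listed markers are argued against, since those markers rose by a median of at most 0.085 CPM per type and the members called higher by 11.4 CPM, although FN1, KRT18, BCL6 and CD68 rose; other cell types were not tested. All 13 members that rose also did so with GC correction, which argues against a GC bias as the whole cause. Whether the whole programme rose stays open: 56.5% of tested members rose and OAS2 (−1.52), OAS3 (−0.60) and IFI35 (−0.48) fell, but with GC correction 15 of 23 rose and of these 3 OAS2 alone was called lower, and no independent test was run. A response to Cfz that reaches only part of this programme is a hypothesis, and IFNL1, an interferon gene below the filter, went from 97 to 35 counts.

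Constitutive proteasome subunit genes rose (31 of 32, median 1.27), as did POMP (1.8, and 1.11 with GC correction), the gene of the core's maturation protein, while 3 of 4 PSMG chaperone genes and 5 of 5 immunoproteasome genes fell and 0 of 4 base assembly chaperone genes passed (median 0.015; with GC correction 2 higher and 1 lower). The difference between the medians of the constitutive genes and of the 9 PSMG and immunoproteasome genes was 1.91, and 1.92 with GC correction. This argues against GC content as the whole cause of the difference. A bootstrap over genes gave a 95% interval of 1.45 to 2.52 with GC correction, which does not measure the spread between libraries. These 9 genes, grouped after their values were seen (8 called lower), had a median of at most −0.55 over 4 scalings. Against the main fit, the scalings moved the median of all genes by −0.27 to 0.084 (log2), too little to bring −0.64 to 0. The fall thus held under each scaling run, but a larger shift between the groups was not tested. The scalings say nothing of the contrast, which scaling cannot alter. The PSMG genes alone had a median of −0.92, and −0.72 with GC correction. For the immunoproteasome alone the median went from −0.40 to −0.17 with GC correction and 3 of 5 genes stayed lower, so GC content may account for part of that fall. A response of PSMG genes to Cfz apart from that of subunit genes is a hypothesis found and tested on the same libraries.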
